A study of Homo sapiens with 24 samples.

How the data were processed

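The series measured RNA and surface protein tags in single mononuclear cells of 12 patients with mixed phenotype acute leukemia, a leukemia whose blasts carry markers of more than 1 blood lineage. Per the labels, cells were frozen, thawed and partitioned with barcoded template particles (PIP-seq), which capture a cell's RNA together with antibody-derived tags (ADT), short DNA barcodes carried by antibodies. The 24 samples are 12 RNA libraries and 12 ADT libraries, 1 of each kind per patient, and a patient's 2 libraries are listed with the same matrix. The titles call the cells stem and progenitor cells, while the protocol describes unsorted mononuclear cells. No label places a patient in a subgroup, so no groups of patients were compared. Each patient supplied 1 library, so differences between patients include differences between library preparations.

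The deposited matrices hold whole-number UMI counts, 1 value per row and cell, not normalized. Per the submitters' processing notes, Seurat 4.3.0 and the genome build GRCh38.p13 were used, with no role given for either. The aligner, the counting tool, the annotation and the rule by which barcodes were kept as cells are not given in the sources used here. Between 9.91% and 23.5% of the listed entries of a matrix were 0 and were dropped. The files used here do not pair matrix rows with gene names, and names were not taken from the order of a reference annotation. The planned comparisons that need names were therefore not run: myeloid with lymphoid transcripts in a cell, stem with lineage transcripts in a cell, list levels across patients, progenitor-like against monocyte-like, T-like and B-like cells, and protein against RNA of a marker.

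The tables of 11 libraries had 60198 rows and that of 1 library had 60199. In blocks of 5000 rows the larger table matched the mean of the others in the same order (lowest Pearson correlation across rows 0.957 over 12 blocks), and at most 0.167 when shifted by 1 row. Over the 179 transcript rows after these blocks, its correlation with the mean of the 11 others was 0.900 in order and at most 0.408 when shifted. With the mean of the 2 other libraries with 19-base barcodes it was 0.997 in order and at most 0.166 when shifted. Each of the last 19 rows was detected in at least 1.78% of cells of each of the 11 libraries, and the row before them in as few as 0.0511%. These end rows, and the last 20 of the larger table, were kept out of the comparisons of transcript rows, leaving 60179 rows. The placing of the extra row among the end rows was not settled, so end rows of that library were not compared with the others. Barcodes had 16 bases in 9 libraries and 19 bases in 3, which was treated as a technical batch.

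Analyses used Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, with fixed seeds. All deposited cells entered the depth values, the summed profiles and the clustering for clusters A and B. The shares of cells in clusters of 1 library used cells with at least 500 transcript UMIs, which were 44.5% of the cells of 1 library and at least 89.8% of those of the 11 others. For profile distances, the cells of a library were split at random into 2 parts, counts were summed, and each sum was thinned to 690000 UMIs. The distance was 1 minus the Spearman correlation over 29690 detected rows, and the pairing of parts was tested one-sided with 100000 permutations, or all pairings below 10 libraries. Biological coefficients of variation came from edgeR on 9461 rows with a mean of at least 10 CPM.

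For clustering, 1170 cells per library were thinned to 500 UMIs, scaled to 10000 per cell and log-transformed. Clusters were found from 2000 variable rows, 30 principal components and 15 nearest neighbours with Leiden resolution 1. A cluster was called a cluster of 1 library when 1 library supplied over 50% of its cells. The way to choose variable rows was not fixed before the data were examined. The first choice, the highest dispersion among rows in at least 3 cells, gave a median share of 12.0% in clusters of 1 library and 27 called rows between the clusters with cells in the most libraries. After those results were seen, 5 ways were compared by how well clusterings of 2 random parts of each cell's UMIs matched. The adjusted Rand index was 0.288 for the first choice and 0.783 for Pearson residuals among rows in at least 0.5% of cells, which was then used. Because differences between libraries can raise this index, it was also taken within libraries, with medians of 0.210 and 0.702. The other 3 ways gave 0.503, 0.686 and 0.731 over all cells, with medians within libraries of 0.398, 0.576 and 0.670. Scrublet marked at most 0.512% of cells in a library and was taken not to have worked, so the 10% of cells with the highest score were left out in an alternative instead.

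For the comparison of clusters A and B, all 73030 cells were clustered on 1 random part of each cell's UMIs and the other part was summed per patient and cluster. The 2 clusters with at least 30 cells in the most libraries were compared with the quasi-likelihood test of edgeR, with TMM factors, filterByExpr and the patient as a block, at a Benjamini-Hochberg adjusted p below 0.05. Both clusters came from the same patients, so the patient pairs the sums, and the same patient's sums deviated together (correlations 0.319 to 0.504 in 6 pairs). The rule for named rows, fixed before the data were examined, took called rows with an absolute log2 fold change of at least 1, a mean of at least 20 CPM in the higher cluster and the same sign in every patient. Of these, at most 2 row numbers per direction are given. In simulated sums for this comparison (525 rows tested), 74 of 100 rows changed 2-fold and 69 of 100 changed 4-fold were recovered. Of these changed rows 81 and 69 passed the filter, with 7 false calls among 150. Changes below 2-fold, the size of most changes called between A and B, were not simulated. The distance was tested on simulated profiles over 29690 rows: with 1 profile for all 12 libraries the permutation p was 0.78, and with 2000 rows changed 4-fold per library it was 1e-05.

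The alternatives were DESeq2, no filter on low counts, no block, other resolutions, other numbers of variable rows, no thinning, other cell and row minimums, each barcode length alone and each library left out. Single-sample values and figures carry no patient number.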

Results

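The 12 RNA libraries of mixed phenotype acute leukemia held 73030 cells and 137 M UMIs. A library had between 1173 and 10315 cells, with a median of 6300, and between 1.79 and 19.9 M UMIs. The median UMI count per cell had a median of 1504.5 over libraries and ranged from 615.5 to 2153. These totals include the end rows, which held 14.7 M UMIs. The transcript rows alone held 123 M, and their median UMI count per cell had a median of 1344.5 over libraries. Cells had a median of 692 detected transcript rows, from 334 to 989 by library. The 10 most abundant rows took 9.39% of transcript UMIs (median over libraries, range 8.19% to 12.2%), and the top 50 took 27.4%. A library had between 20404 and 29515 detected rows, and 36882 rows were detected in at least 1 library. With 16-base barcodes the median transcript UMI count per cell averaged 1306 ± 464 (SD, n = 9), and with 19-base barcodes 1290.5 ± 193 (SD, n = 3).

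The first comparison asked how far the mononuclear cells of different patients differed in their summed RNA profiles beyond sampling. All deposited cells were summed with no cell type assigned, so leukemic cells were not told apart from others. Profiles of different libraries, each from 1 patient, were 1.72 times as far apart as profiles of random parts of 1 library. The mean distance, 1 minus the Spearman correlation, was 0.181 ± 0.0372 (SD, n = 66 pairs) between libraries and 0.105 ± 0.00668 (SD, n = 12) within a library. The size of the ratio depended on the measure: it was 5.18 over rows with a mean of at least 10 CPM and 5.34 with the Pearson correlation of log2(CPM + 10). In 12 of 12 libraries the nearest profile was the other part of the same library (permutation p = 1e-05, one-sided, the smallest that 100000 permutations can give). This test sets separate libraries against the sampling of cells and UMIs within a library, so it does not separate patients from library preparations. The biological coefficient of variation was 0.575 between libraries and 0.0648 between parts of a library.

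The mean distance between libraries was 0.175 ± 0.0380 (SD, n = 36 pairs) among 16-base libraries and 0.163 ± 0.00834 (SD, n = 3 pairs) among 19-base libraries. For the 16-base libraries the exact permutation p was 2.76e-06, while 3 libraries cannot give less than 0.167. The coefficient of variation was 0.539 with barcode length as a term, 0.548 within 16-base libraries and 0.495 within 19-base libraries. In a comparison added after the data were seen, libraries with different barcode lengths were on average 0.192 apart and those with the same length 0.174, a difference that 55 of the 220 choices of 3 libraries matched or passed (exact permutation p = 0.25, one-sided). This rested on 1 library: without the one with the fewest cells the means were 0.180 and 0.158, and 1 of 165 choices, the real one, was as large (exact permutation p = 0.00606, one-sided). With any other library left out the p was between 0.158 and 0.279. The library with the fewest cells stood farthest from the others, at a mean distance of 0.251 against 0.190 for the next, and without it the ratio was 1.59.

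**Figure D1:**
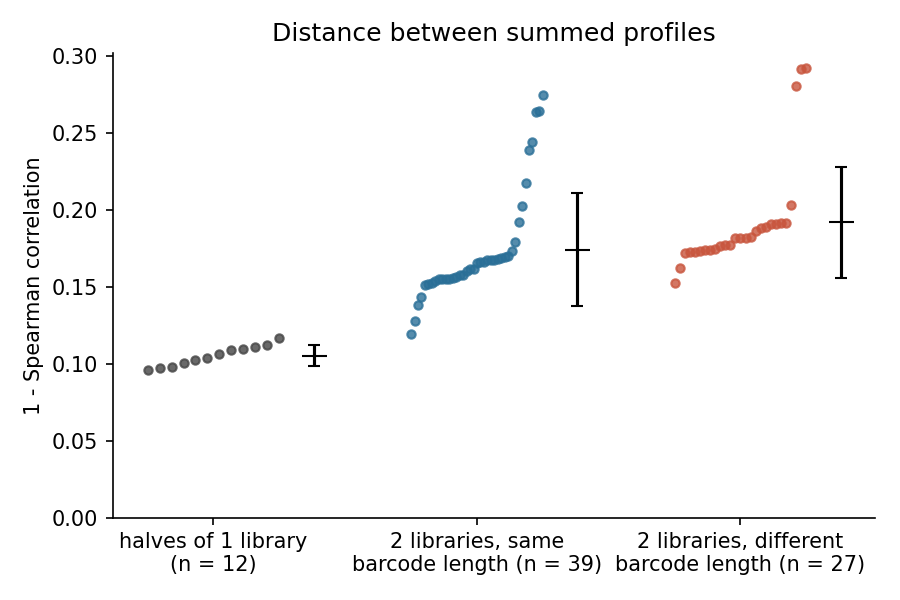
Distance between summed RNA profiles (vertical axis, 1 minus the Spearman correlation, no unit) for random parts of 1 library (12 points) and for 2 libraries with the same (39 pairs) or different (27 pairs) barcode length. Points are sorted by value, bars give the mean ± SD, and the within-library values, with a mean of 0.105, lie below all distances between libraries.

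The second comparison asked which cells formed states specific to 1 patient and which lay in states shared by patients. Most libraries had most of their cells in clusters that 1 library filled. Of 19 clusters, 13 drew over 50% of their cells from 1 library, and 9 drew over 90%. The median library had 86.5% of its drawn cells, all with at least 500 transcript UMIs, in such clusters, with a range from 6.07% to 97.8%. A library's share counts its cells in any such cluster, also where another library filled it. It is thus not the share in states specific to that patient. For example, 1 library had a share of 75.9%, although the only cluster it filled held 371 cells, against 1170 cells drawn per library. In 9 of 12 libraries the share was over 50% and in 7 it was over 80%, while 3 libraries had less than 25%. The low shares depended on the clustering. The lowest share of a library was 61.3% at Leiden resolution 2, 56.8% with 4000 variable rows, 61.2% in cells not thinned and 57.5% among 16-base libraries alone, but 0.940% at resolution 0.5 and 1.37% with 1000 variable rows. The remaining 6 clusters were shared, and the one with the widest spread held at least 10 cells of 11 libraries. Among the 15 nearest neighbours of a cell, 76.6% ± 13 (SD, n = 12 libraries) came from its own library, against 8.26% with permuted library labels.

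The median share was 84.4% among 16-base libraries alone and 91.3% among 19-base libraries alone. It was 90.9% in cells not thinned to 500 UMIs, while the mean share over libraries was 89.1% there and 68.5% in thinned cells. The share depended on how variable rows were chosen, a choice settled after first results were seen: with rows of high dispersion in at least 3 cells, the median fell to 12.0%.

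**Figure D2:**
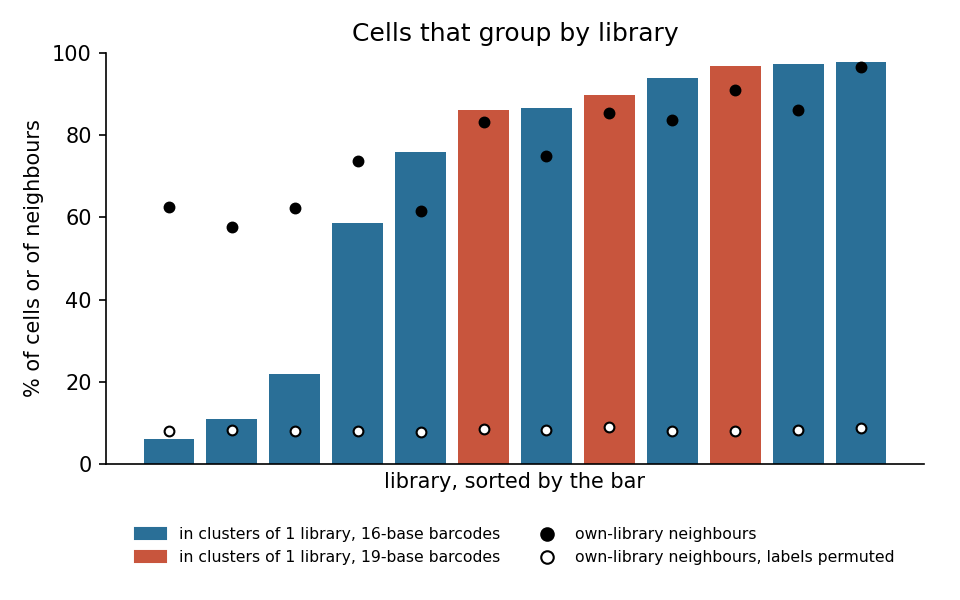
Share of each library's 1170 cells in clusters that 1 library, its own or another, fills (bars, %, coloured by barcode length) and mean share of own-library cells among a cell's 15 nearest neighbours (filled points, %, and open points for permuted library labels). Libraries are sorted by the bar; 3 libraries lie below 25% and 9 above 50%, and the filled points of all 12 libraries lie above 57%.

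The third comparison asked which transcript rows differed between 2 clusters, called A and B, in the same patients. These were the clusters with at least 30 cells in the most libraries, a rule that sets no limit on the share of 1 library. Of 639 rows tested in 6 patients, 97 passed an adjusted p of 0.05 in edgeR, 61 higher in B and 36 lower. Of the called rows, 7 differed by at least 2-fold, and the median absolute log2 fold change of called rows was 0.56. The median of all tested rows was -0.06. Row 3097 rose from 107 ± 34.7 CPM in A to 246 ± 63.5 CPM in B (SD, n = 6), a log2 fold change of 1.10 with a standard error of 0.32 (adjusted p = 0.0166 in edgeR). Row 28629 rose from 123 ± 50.1 to 262 ± 62.1 CPM (log2 fold change 1.02, SE 0.30, adjusted p = 0.0200 in edgeR). Row 59589 was at 425 ± 92.9 CPM in A and 203 ± 59.4 CPM in B (log2 fold change -1.12, SE 0.25, adjusted p = 0.00150 in edgeR). Row 60144 was at 768 ± 259.9 CPM in A and 387 ± 144 CPM in B (log2 fold change -1.09, SE 0.20, adjusted p = 0.000150 in edgeR). Each of these 4 rows moved the same way in 6 of 6 patients, which the rule for named rows required. Leaving out 1 patient ended the call of row 3097 (log2 fold change 0.92), and leaving out another ended that of row 28629 (0.88). The calls of all 4 rows ended without the filter on low counts, where their log2 fold changes moved up by 0.42 to 0.64, to -0.54 for row 59589 and -0.45 for row 60144. They also ended among the 16-base libraries alone and without the block, where the sizes were 0.97 to 1.14 and 0.92 to 1.15. Row 60144 was not a single change: of the last 50 transcript rows, a stretch picked out after its values were seen, 12 were tested, and all 12 were called lower in B, with log2 fold changes from -1.09 to -0.59. These 50 rows held 3.56% ± 1.16 of transcript UMIs in A and 2.17% ± 0.777 in B (SD, n = 6), lower in B in 3 of 3 patients with 16-base and 3 of 3 with 19-base barcodes. The other 24 rows called lower lay elsewhere. The rows carry no gene name here, so no cell type is assigned to either cluster.

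Cluster A held 5368 cells, at least 30 of them in each of 9 libraries, and 1 library, which had too few cells in B to enter the test, supplied 53.7%. By the 50% rule of the second comparison A was thus a cluster of 1 library. With libraries weighted equally that library supplied 41.9%. Cluster B held 2464 cells, with at least 30 in each of 7 libraries and 45.2% from 1 library. Cells of B had more transcript UMIs, 1221 ± 99.4 per cell against 905 ± 135 in A (SD, n = 6), 1.36-fold higher and higher in 6 of 6 patients (exact sign-flip permutation p = 0.0312, two-sided, the smallest possible). The ratio was 1.45 with 16-base and 1.27 with 19-base barcodes, 3 patients each. Clusters A and B came from cells that were not thinned, so depth can decide which cells enter them. Neither this ratio nor the comparison of rows was repeated with clusters of thinned cells. The summed counts behind a value ranged from 14528 to 716636 UMIs, so rows of low abundance were not tested. Without the patient as a block edgeR called 0 rows, with 120 at an unadjusted p below 0.05, while DESeq2 with the block called 86. Without the filter on low counts edgeR called 2 rows, both lower in B and neither among the 97. The median log2 fold change of all rows was 0.26 in that setting. Without normalization factors 92 rows were called, 33 higher in B and 59 lower, so the balance of directions depended on the scaling. At Leiden resolution 0.5, where the clusters chosen by the same rule were others, 1791 of 5703 rows were called in 6 patients, 1372 of them at least 2-fold. These 6 patients all had 16-base barcodes and were only in part those compared for A and B. At that resolution A and B may have been joined in 1 of the clusters compared, which was not tested cell by cell. In 1 patient A and B held 112 and 1114 cells, and that cluster held 1271. In another they held 37 and 882, and it held 930, but in a further patient 407 and 60, and it held 2451. Within barcode lengths, 13 rows were called in 3 patients with 16-base barcodes and 30 in 3 with 19-base barcodes. With the first choice of variable rows the clusters chosen were also others, and 27 of 1357 rows differed over 12 patients.

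**Figure D3:**
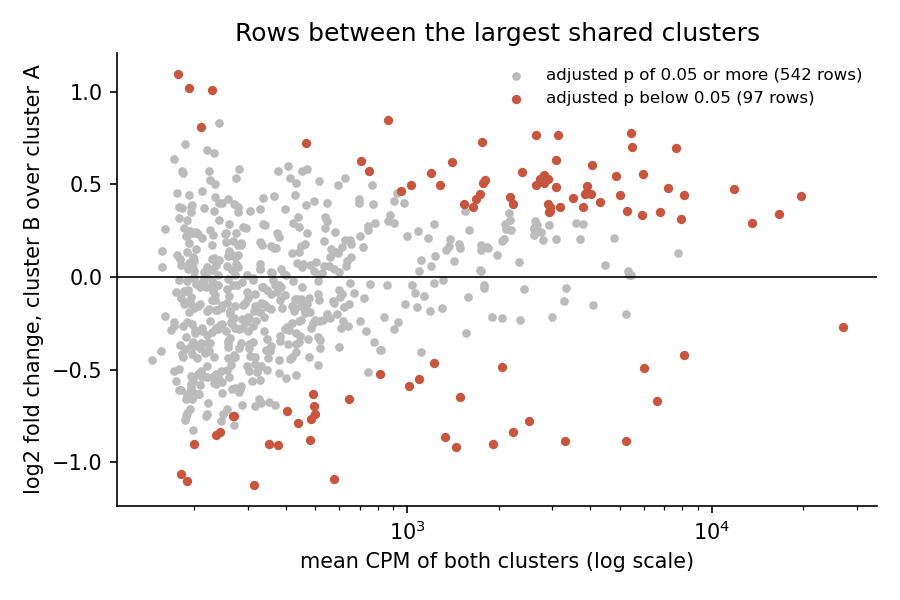
Log2 fold change of cluster B over cluster A (vertical axis) against mean CPM of both clusters (horizontal axis, log scale) for 639 rows tested in 6 patients, 1 point per row. Coloured points are the 97 rows with an adjusted p below 0.05, 61 above and 36 below 0.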

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

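The tests of barcode length and depth for the grouping of cells, the tests of the nearly empty rows, and the swap test of clusters A and B were chosen after the results were seen.

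The last rows of the tables, which were kept out of the comparisons of transcript rows, held a median of 11.7% of a library's UMIs, from 3.34% to 22.7%. If these rows come from a separately prepared library, such as antibody tags, their UMIs in a cell should follow the cell's other UMIs loosely. In 11 of 11 libraries they did so less closely than each of 20 random sets of rows with the same total. The median Spearman correlation over cells was 0.190 (range 0.0189 to 0.293), against 0.964 for random sets. The random sets matched the end rows in total UMIs but not in number of rows. Within a library, the largest end row held 21.7% to 70.9% of end-row UMIs. A sum over few rows can follow depth loosely whatever its source, so the test cannot decide whether these are antibody tags. The rows have no names here, and a small group of rows tied to cell type was not tested as another source.

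The grouping of cells by library has technical and patient explanations that the design, with 1 library per patient, leaves entangled. Barcode length alone would have lowered the median share below 43% in the 16-base libraries, where it was 84.4%. Unequal depth as the main source would have lowered the median by over 50% on thinning, but it was 86.5% with every cell thinned to 500 UMIs and 90.9% without. The mean share over libraries was 68.5% with thinning and 89.1% without, and the lowest share of a library 6.07% and 61.2%. A contribution of depth in the libraries with low shares thus stays open. A shift of all cells of a library, from free RNA or library chemistry, may contribute: in shared clusters, own-library neighbours exceeded the share given by the cluster's make-up by 26.1 percentage points ± 10.0 (SD, n = 11 libraries), above the bound of 20 set before, by less than its spread. Patient-specific states inside shared clusters would give the same excess, so a patient effect stays open and no biological explanation was tested.

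Rows nearly empty with 1 barcode length occurred both ways: of 8562 rows with at least 5 CPM in each of the 3 libraries with 19-base barcodes, 22 were below 1 CPM in all 9 others, against at most 6 for another choice of 3 libraries. In the direction tested further, of 7779 rows with at least 5 CPM in each of the 9 other libraries, 7 were below 1 CPM in all 3, and 6 of these lie between rows 60150 and 60179. Among 220 choices of 3 libraries, 1 (the real one) gave as many, and the highest other gave 2. Low depth would have left at least as many such rows in the 3 libraries with the fewest transcript UMIs, none of them with 19-base barcodes, and these had 0, which argues against depth. A difference in library chemistry or in the set of counted features may be the source, but was not tested, and the 3 patients cannot be separated from the barcode length.

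Among the 32 ways to swap clusters A and B within the 6 patients, 1 (the real one) gave 97 rows, and the highest other gave 11. Clusters A and B were found from transcripts of the same cells and so differed by construction. The swaps therefore cannot decide whether chance contributed to that count.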

How the results depend on the processing

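The way to choose variable rows, the 1000-UMI minimum, the doublet score, the second draw of cells, the row sets by barcode length, each barcode length alone, Pearson with 1 added, the lack of normalization factors, leaving out libraries for clusters, the comparison by barcode length, and all settings of one-library against shared clusters were chosen after the data were seen. Depth per cell and rows per cell moved by less than the spread between libraries under both alternatives. The ratio of distances kept its direction and its side of the threshold in 17 of 18 alternatives (1.59 to 1.76 with a library left out, up to 5.34 with other measures). Among 19-base libraries alone it was 1.57, where 3 libraries cannot pass the threshold. The difference by barcode length, 0.0177, passed it in 1 of 12 alternatives, without the library with the fewest cells (0.0219, exact permutation p = 0.00606, range over alternatives 0.00606 to 0.279). The median share of cells in clusters of 1 library stayed between 68.0% and 93.6% in 18 of 19 alternatives and was 12.0% with variable rows chosen by dispersion in at least 3 cells. The cause was not tested.

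For clusters A and B the count of 97 rows stayed within 1.5 times under 8 of 14 alternatives (66 to 90 with a library left out). It was 0 in edgeR with no replicate block, where the pairing of patients is left out (120 at an unadjusted p below 0.05), while DESeq2 with the block called 86. The count was 2 with no filter, where 19145 rows were tested and neither of the 2 was among the 97. At Leiden resolution 0.5, with other clusters, 1 of which may have joined A and B, and in part other patients, the count was 1791. It was 27 with variable rows chosen by dispersion, 13 among 16-base and 30 among 19-base libraries, each with 3 patients. Requiring at least 100 cells left 1 patient and gave no value. The 4 named rows kept their direction in every alternative that tested them between clusters A and B. Their direction in the alternatives with other clusters was not compared. None of the 4 passed the threshold without the filter, without the block or among 16-base libraries alone. Their log2 fold changes had sizes from 0.92 to 1.15 in the last 2 settings, while without the filter all 4 shifted upward by 0.42 to 0.64. DESeq2 gave an adjusted p to row 60144 alone of the 4, and called it. The call of row 3097 also ended without 1 patient (edgeR adjusted p 0.132, range over alternatives 0.0224 to 0.992) and that of row 28629 without another (0.0622, range 0.0275 to 0.992). Neither was tested without a further patient or among 19-base libraries alone, where row 59589 was not called. Without normalization factors the median log2 fold change of all rows moved from -0.06 to -0.17.

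For cells of one-library against shared clusters, 1746 rows became 3470 with no filter, 631 with no replicate block, 860 among 16-base and 706 among 19-base libraries, and 1298 to 1945 with a library left out. The alternatives for results that need gene names were not run.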

Other observations

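All comparisons in this part were chosen after the data were seen. Cells in clusters of 1 library, with libraries weighted equally, were set against cells of the same patient in shared clusters. The library that filled a cluster could be that of another patient. The clusters came from 1 part of each cell's UMIs and row tests from the other. Cells of one-library clusters had more transcript UMIs, with a mean of the library medians of 1403 ± 420 against 1038 ± 304 (SD, n = 12 patients), 1.33-fold higher and higher in 12 of 12 patients (exact sign-flip permutation p = 0.000488, the smallest possible, adjusted 0.00146 over 3 quantities). These classes came from clusters of cells that were not thinned, so depth can decide which cells enter them. With the clusters of cells thinned to 500 UMIs the ratio was 1.15, higher in 8 of 11 patients, and did not pass the test (exact permutation p = 0.104). The comparisons of rows below were not repeated with those clusters. At 500 UMIs per cell the cells of one-library clusters also had more detected rows, 351 ± 17.5 against 327 ± 34.0 (higher in 10 of 12 patients, exact permutation p = 0.00879, adjusted 0.0132). The ratios within 16-base libraries were 1.37 for UMIs (exact permutation p = 0.00391) and 1.09 for rows (exact permutation p = 0.0273). Within 19-base libraries they were 1.23 and 1.04, where 3 patients cannot give a p below 0.25. UMIs in the end rows did not pass the test (191 ± 72.2 against 188 ± 103, higher in 8 of 12, exact permutation p = 0.561).

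A minority of transcript rows differed between these 2 classes of cells, and their direction in each single patient was not counted. In edgeR with the patient as a block, 1746 of 9460 rows passed an adjusted p of 0.05, 981 higher in one-library clusters and 765 lower, 401 and 494 of them by at least 2-fold. Without the block 631 passed. Without normalization factors the split was 1434 higher and 522 lower, with the median of all rows at 0.26 in place of 0.10, so the balance of directions depended on the scaling. Within barcode lengths 860 rows passed in 9 patients and 706 in 3. Of 50 drawn ways to swap the classes within patients, 1 (the real one) gave as many rows. The highest other, 1517, swapped 1 patient, and 2 of the 49 others called any row. Not all ways were drawn, and the classes came from clustering transcripts of the same cells, so the swaps cannot exclude chance for the count. The count also says nothing on which cells are leukemic. In simulated sums for this comparison (8672 rows tested), 59 of 100 rows changed 2-fold and 93 of 100 changed 4-fold were recovered. Of these changed rows 84 and 93 passed the filter, and 3 of 155 calls were false. Changes below 2-fold were not simulated.

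Among the 19 end rows, 7 passed an adjusted p of 0.05 as a share of end-row UMIs in 11 patients (exact sign-flip permutation tests), 6 lower in one-library clusters and 1 higher. The lowest fell by 2.75 ± 1.13 on the log2 scale (SD, n = 11), lower in 11 of 11 patients, and the highest rose by 1.02 ± 1.02, higher in 10 of 11. Counted per cell, 7 rows passed, 5 lower and 2 higher. These shares are on a scale with 1 count added.

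The share of own-library neighbours had no detectable relation to the median transcript UMI count per cell, with Pearson r = 0.279 (permutation p = 0.382, adjusted 0.636) and Spearman rho = 0.175 (permutation p = 0.588, adjusted 0.882) over 12 libraries and 3 relations. Without the 2 libraries farthest from the median depth r was 0.0326, and within 16-base libraries r was 0.364.

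The totals of the 4 deepest libraries lay between 19.8 and 19.9 M UMIs, a range of 0.515%, although their cells numbered from 9033 to 10315. The next library had 13.1 M.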
